A study of Halobacterium salinarum NRC-1 with 28 samples.

How the data were processed

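The samples were RNA from a ura3 knockout of the archaeon Halobacterium NRC-1, an extreme halophile, grown without added metal or exposed to manganese (Mn) or copper (Cu). Each RNA sample was hybridised on 2-colour arrays against a common reference that the labels name only as control RNA of NRC-1. The 28 arrays held 14 RNA samples, each on 2 arrays with the dyes exchanged. There were 7 groups of 2 samples, called set A and set B: unstressed, Mn at 0.8, 1.0 and 1.5 mM, and Cu at 0.7, 0.85 and 1.0 mM. The labels do not say what a set is, so p-values measure only the spread between these samples, which may be technical. Groups follow the titles, source names and descriptions. On the arrays with sample RNA in channel 2 the growth protocol names an iron sulfate exposure instead, and this conflict stays open.

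The values are a deposited score per spot, a signed log ratio of the dye channels. Its log base, its numerator and any centring by the authors are not given in the sources used here. Values are therefore printed in deposited log-ratio units, with no folds. The design had assumed log2 values, and the same test was run on the deposited units, since its statistics do not depend on the base. Column medians as deposited lay between 0.122 and 0.184 on 27 arrays and at 0 on the remaining array, so the columns had not been centred. Scanner images and spot intensities were not analysed here, so signal over background is unknown, and precision is limited by the number of arrays.

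Every array had 10752 spots, read as 2688 features of 4 spots each by a position rule that held for all 133 features with a gene symbol (532 spots with 1 symbol each and none with several). The remaining 2555 features have no symbol in the annotation used here, which is old, and are called by their first spot number. The reference gene table given for this organism is of strain 91-R6, and was not used for coordinates. Exact 0 values were read as spots with no ratio. The array of Mn 1.0 mM set A with sample RNA in channel 2 had 6633 such spots (61.7%), the others at most 335, and 1281 of the 2688 features kept a ratio in that sample. Reading 0 as missing was decided after the values were first examined, with 0 kept as an alternative. The spots left on that array had a median of 0.02, against 0.122 or more on the others, so centring it on a selected part of the spots can shift this sample.

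Each array was centred on its median and the spots of a feature were averaged. The ratio of an RNA sample was the mean of its channel-1 array and its channel-2 array with the sign turned. The design had planned to read from the correlation between the 2 arrays of a sample whether the deposit was already turned. That correlation was 0.33 to 0.884, which by itself reads as turned. Dye effects common to all arrays would give such values too if the deposit was not turned. The correlation cannot tell these readings apart, so it did not decide. The agreement between the sets did not decide either (median correlation of deviations 0.277 turned, 0.252 unturned). Group differences were then computed in each dye orientation apart. After turning, they correlated across features at 0.427 for Mn against unstressed and 0.448 for Cu against Mn (Spearman 0.304 and 0.35). Values turned before deposit would give correlations below 0, so the values were taken as not turned. The consensus correlation of the 2 turned arrays of a sample, after group and dye terms, was -0.12. A value below 0 there leans the other way, so the turning is likely and not settled. The test by orientation was chosen after the data were seen, and features are not independent replicates.

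The direction is likely, not settled. Channel 1 was taken as the numerator because the descriptions always name its RNA first, and because the deleted gene then lies below the reference. If channel 2 is the numerator, every direction in the text reverses and every size and p-value stays.

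Differences were tested with limma (version 3.58.1, in R 4.3.3) over all 14 RNA samples with 1 mean per group, least squares per feature, empirical Bayes variances (7 residual and 18.6 prior degrees of freedom) and Benjamini-Hochberg adjustment over features. A feature was called at an adjusted p under 0.05. Errors of differences are standard errors (SE) of this fit. The unstressed group was also tested against 0, that is against the reference, which counts as 1 control sample and leaves out its own spread. The test was tried on simulated data with the real missing values. Noise was normal and independent between features, with the empirical Bayes variance of each feature in all groups. Spread that differs between groups and features that vary together were not simulated. Of 200 changed features, 35.6% were recovered at a difference of 0.1 and 98.5% at 0.2 for Mn against unstressed, 38.3% and 98.7% for Cu against unstressed, and 20.4% and 90.7% for Cu 1.0 against 0.7 mM (2688 features, 20 simulations each). Fewer changed features would make the adjusted threshold stricter and lower these shares.

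Of 22 gene lists fixed before the data were examined, 9 had no member among the 133 symbols. Lists with 5 or more members were tested with limma's camera at a preset correlation of 0.01 against the named genes, with camera at an estimated correlation and fry beside it, both over 13 samples (without Mn 1.0 mM set A). Another 4 lists (aminoacyl-tRNA synthetases, histidine synthesis, citric acid cycle and 2-oxoacid oxidation, other amino acid synthesis) were made after the values were first seen, as was the choice of the named genes as background. Together 7 lists were tested in each of 4 comparisons.

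Named genes follow a rule fixed before the data were examined. In the 4 main comparisons it takes the 10 largest called changes in each direction that have the same sign in both sets, and in the others the 3 largest. For the means of each metal it adds up to 4 members of each fixed list, and always pyrF and dpsA; other metal genes it asked for had no symbol here. Where nothing passed, the 5 smallest p are named. The rule was applied to genes with a symbol, with at most 2 features without one per direction, a split made after the files were seen. Alternatives fixed beforehand were the set as a block, each array as an observation with a dye term (statmod 1.5.0), no centring, scaling, either dye orientation alone, the median of spots, the compared groups alone, complete features alone and leaving out each sample. Added after the data were seen were 0 values kept, values taken as already turned, and all features as the background of the list tests.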

Results

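Transcript levels were measured on 2-colour arrays in 14 RNA samples of a Halobacterium NRC-1 ura3 knockout, 2 samples in each of 7 groups: unstressed, 3 doses of Mn and 3 doses of Cu. Each sample was hybridised on 2 arrays, with dyes exchanged, against a common control reference. The comparisons address how transcript levels differ between the metals, between doses, and between the knockout and the reference. Values are deposited log-ratio units of unstated base, sample over reference, with the likely direction that takes channel 1 as numerator. If that is wrong, all directions reverse. The turning of the dye-exchanged arrays is also likely and not settled. Taken as already turned, 23 features were called for the Mn mean and 64 for Cu against Mn. Of these, 0 and 1 were among the 120 and 349 calls below with the same direction, so the results would then not hold. Of 2688 features, 133 carried a gene symbol.

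The deleted gene was examined first. The gene symbol pyrF denotes orotidine 5'-phosphate decarboxylase of pyrimidine synthesis, also called ura3. Its ratio lay below 0 in 13 of 13 samples with a value, with a mean of -0.14 (SD 0.071) and a range of -0.32 to -0.0011. This is also a basis of the likely direction, so it is no separate check of it. The size was small for a deleted gene: 64 features had a lower mean over the 7 groups, and pyrF lay at the percentile 4.5 of features in the median sample. The position of its probe within the gene is not given in the sources used here, and a probe outside the deleted part would check nothing.

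Without added metal, genes of purine synthesis were higher in the knockout than in the reference. Of 7 named members of that list 4 were higher and 3 did not pass (5 higher when adjusted over the list alone): purF, the amidotransferase that opens the pathway, by 0.27 (SE 0.031), purL by 0.25 (SE 0.029), purM by 0.18 (SE 0.03) and purD by 0.16 (SE 0.038). Higher too were arcA (arginine deiminase) at 0.19 and arcC (carbamate kinase) at 0.17, both members of the list of arginine fermentation, and carB, the large subunit of carbamoyl-phosphate synthase, at 0.15. Lower were rpl12p, a ribosomal protein, at -0.16 (SE 0.03), speB (agmatinase) at -0.14, cbiT of cobalamin synthesis at -0.13, sucD (a subunit of succinyl-CoA synthetase) at -0.13 and htr2, a transducer of taxis, at -0.12. The transducer htr6 was higher at 0.13.

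In all, limma called 308 features in that comparison, 126 higher and 182 lower, with 25 named genes among them. Camera placed the purine list above other named genes (adjusted p = 1.47e-05), also with an estimated correlation (adjusted p = 0.0244), but that call was lost against all features as background (adjusted p = 0.055 with an estimated correlation). Without unstressed set A 43 features were called, 29 higher and 14 lower, so the balance of directions turned, and the calls of carB, purD, htr6, gdhA1, argH, rpmC and pyrF ended without either of the unstressed samples in turn, and those of arcC, rpl12p, speB, cbiT, sucD and htr2 without unstressed set A; purF, purL, purM and arcA stayed called without either. In a single dye orientation the dye effect does not cancel against 0, and signs of several of these genes turned.

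Under Mn, purine synthesis genes fell. The mean of the 3 doses lay below unstressed by -0.37 for purF (SE 0.038, adjusted p = 2.62e-07), -0.33 for purL (SE 0.034, adjusted p = 2.62e-07), -0.26 for purM (SE 0.034) and -0.19 for purD (SE 0.043). Of the 7 purine members 4 fell and 3 did not pass, or 5 fell when adjusted over the list alone. For purL and purM, 6 of 6 Mn samples lay below both unstressed samples, and for purF 5 of 5 with a ratio. Camera gave the list an adjusted p of 1.39e-05, and 0.0226 with an estimated correlation (adjusted p = 0.021 against all features).

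Other named genes that fell under Mn were carB by -0.27 (SE 0.037), gdhA1 (glutamate dehydrogenase) by -0.25 (SE 0.035), rpl12p by -0.22 (SE 0.035), phoU, a regulator of phosphate uptake, by -0.16 (SE 0.037), arcC by -0.16 (SE 0.039) and dpsA, a ferritin-like protein that stores iron and protects DNA, by -0.15 (SE 0.036, adjusted p = 0.0129). Only ppsA (phosphoenolpyruvate synthase) rose among named genes, by 0.13 (SE 0.034, adjusted p = 0.0221). Among features without a symbol, feature1007 rose by 0.69 (SE 0.034), feature903 rose by 0.44, and feature4291 and feature4007 each fell by 0.37. In the pyrimidine list carB was the 1 of 5 members that fell, while carA differed by -0.064 and pyrI by -0.04 without passing. None of the 4 members of chaperones and proteasome passed, with dnaJ at -0.064 and dnaK at -0.064, nor did the 4 of DNA repair (uvrB at -0.075), the 4 of cobalamin synthesis (cobN at -0.038), the 4 of purple membrane and carotenoids (bat at -0.029) or the 2 of the respiratory chain (sdhC at -0.039). Flagella and chemotaxis had 0 of 11 members called, although camera placed the list above other named genes (adjusted p = 0.0387). The camera call was lost with an estimated correlation (adjusted p = 0.177) and against all features (adjusted p = 0.165). Fry, which does not rank a list against other genes, called flagella and chemotaxis higher (adjusted p = 0.0433). It called the purine list (adjusted p = 0.000208) and the pyrimidine list (adjusted p = 0.0381) lower.

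The Mn comparison called 120 features, 40 higher and 80 lower, of which 12 were named. It tested 2687 features, or 1281 with Mn 1.0 mM set A as the only Mn 1.0 mM sample. Without the Mn 1.0 mM set A sample, whose channel-2 array had most spots at 0, it called 179 (84 higher and 95 lower), and with that sample as the only Mn 1.0 mM sample 254 (51 higher and 203 lower). It called 79 without unstressed set A and 43 (20 higher and 23 lower) without unstressed set B, and the calls of dpsA and phoU ended without unstressed set B, those of purD and arcC without either in turn. The call of ppsA ended without unstressed set A (adjusted p = 0.454), Mn 0.8 mM set B or Mn 1.5 mM set A, and also in a fit of the compared groups alone (adjusted p = 0.0849), with 0 values kept (adjusted p = 0.0578) and in each dye orientation alone. That of arcC ended in the compared groups alone too (adjusted p = 0.0588). In each dye orientation alone the calls of phoU (-0.15 in channel 1 and -0.17 in channel 2) and dpsA (-0.14 and -0.15) ended at about the same size. In channel 1 alone those of purM (-0.11), purD (-0.086) and arcC (-0.075) ended with smaller values, and purF was at -0.23, still called. In channel 2 alone those of arcC (-0.24) and rpl12p (-0.19) ended.

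**Figure D1:**
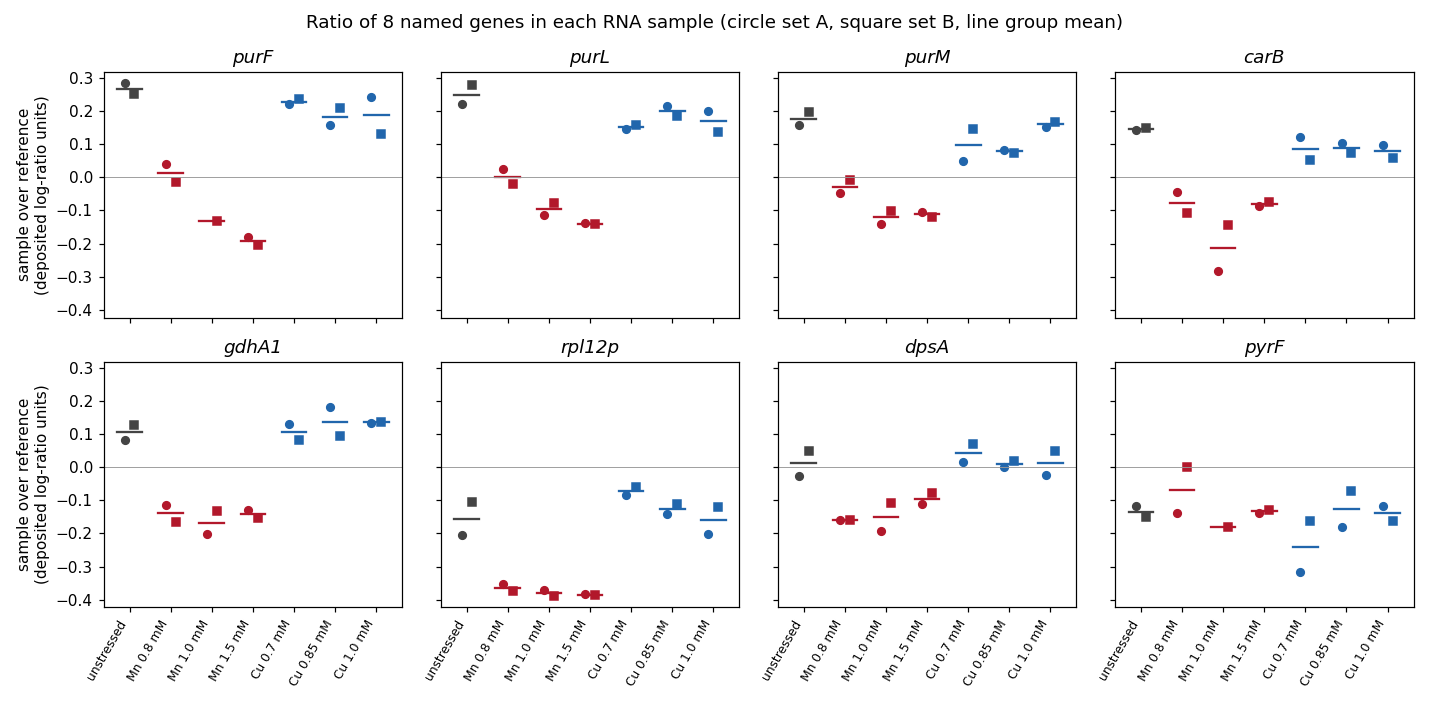
Ratio of 8 named genes (vertical axis, sample over reference in deposited log-ratio units) in each RNA sample of the 7 groups (horizontal axis); circles are set A, squares set B and lines group means. In purF the unstressed mean is 0.27, the Mn means lie between -0.19 and 0.014, and the Cu means lie between 0.18 and 0.23.

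Each Mn dose was also set against unstressed. At 0.8 mM 71 features were called (27 higher and 44 lower), at 1.0 mM 104 (25 higher and 79 lower) and at 1.5 mM 81 (36 higher and 45 lower). Without unstressed set B they called 26 (14 higher and 12 lower), 43 (14 higher and 29 lower) and 44 (23 higher and 21 lower). Without unstressed set A the higher doses called 69 and 48. At 0.8 mM 33 were called without its set A and 43 without its set B, and at 1.5 mM 29 (14 higher and 15 lower) and 42. With complete features alone 1.5 mM called 38 higher and 22 lower, without centring 1.0 mM called 37 higher and 56 lower, and in channel 2 alone 0.8 mM called 30 higher and 25 lower. The balance of directions at a dose thus depends on the setting. The differences of purL were -0.25 (SE 0.041), -0.34 (SE 0.041) and -0.39 (SE 0.041) in that order of dose; in channel 1 alone the call at 0.8 mM ended (-0.20, adjusted p = 0.0714). For purF the group means were 0.014 (SD 0.038, n = 2) at 0.8 mM, -0.13 (n = 1) at 1.0 mM and -0.19 (SD 0.017, n = 2) at 1.5 mM. The direct test of 1.5 against 0.8 mM gave -0.21 for purF (SE 0.044, adjusted p = 0.0629) and -0.14 for purL (SE 0.041, adjusted p = 0.154), so neither passed. The purF difference passed without centring (adjusted p = 0.0441) and with the set as a block. In a fit of those 4 samples alone purF (adjusted p = 0.000854) and purL (adjusted p = 0.0225) both passed. The 1 feature called, feature3583, differed by -0.25, and its call ended when any 1 of the 4 samples was left out (adjusted p from 0.0725 to 0.575), with scaling, with the median of spots, with 0 values kept and in each dye orientation alone. By limma 432 features had an unadjusted p under 0.05 there against 134.4 by chance, and the fit of those 4 samples called 201. At 1.0 mM, 1281 features were tested with set A as its only sample, and 2687 with both. Without the Mn 1.0 mM set A sample the 1.0 mM dose called 122 features, 65 higher and 57 lower, and with it alone 538, 26 higher and 512 lower.

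Under Cu, no named gene passed the test. The smallest p among named genes belonged to thiL (thiamine-monophosphate kinase) at -0.097 (SE 0.036), purL at -0.076 (SE 0.034), htr2 at 0.075 (SE 0.033), speB at 0.072 (SE 0.033) and mamA at -0.069 (SE 0.036), each with an adjusted p of 0.858. The 7 purine members had a median difference of -0.02, and dpsA differed by 0.01 (SE 0.036). Among features without a symbol feature1107 rose by 0.20 (SE 0.036) and feature4291 fell by 0.20 (SE 0.036), each with an adjusted p of 0.0122 and beyond both unstressed samples in 6 of 6 Cu samples. In channel 1 alone feature1107 was at 0.038 (adjusted p = 0.996) and in channel 2 alone at 0.37 (adjusted p = 0.0098), and it was not called with each array as an observation (adjusted p = 0.145). The call of feature4291 ended in channel 1 alone (-0.14, adjusted p = 0.93) and in channel 2 alone (-0.26, adjusted p = 0.53). With 0 values kept neither was called (adjusted p = 0.152 and 0.174).

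These were the 2 features that limma called for the mean of the Cu doses, and 154 had an unadjusted p under 0.05 against 134.4 by chance. Leaving out unstressed set B, or set A of any Cu dose, left 0 calls. Without unstressed set A 2 were called, both lower, and feature1107 was not among them. At 0.7 mM and 0.85 mM limma called 0 features, with 192 and 114 at an unadjusted p under 0.05, and at 1.0 mM it called 1, feature1107, with 61. That call ended without any 1 of the 4 samples compared, with scaling, with the median of spots, with 0 values kept, with each array as an observation and in channel 1 alone (0.034). Without unstressed set A 2 features were called at 0.7 mM and 2 at 0.85 mM. Cu at 1.0 against 0.7 mM gave 0 calls, with 58 at an unadjusted p under 0.05 against 134.4 by chance. The 61 at 1.0 mM and the 114 at 0.85 mM also fell short of that number, while the 192 at 0.7 mM exceeded it. Such a shortfall can mean that the test is too strict there, and its cause was not tested. In simulated data with 200 features changed at once, the test of the Cu mean recovered 38.3% of differences of 0.1 and 98.7% of those of 0.2. Most differences of 0.1 or less would thus be missed. Few features were called under Cu, so the real threshold was stricter and recovery at 0.2 may be lower.

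Between the metals, Cu samples had the higher ratio for most called genes. The differences, Cu minus Mn, were 0.30 for purF (SE 0.028), 0.27 for gdhA1 (SE 0.025), 0.26 for rpl12p (SE 0.025), 0.25 for purL (SE 0.024), 0.21 for carB (SE 0.026), 0.20 for purM (SE 0.024), 0.17 for purD (SE 0.031), 0.16 for arcC (SE 0.028), 0.16 for dpsA (SE 0.025) and 0.15 for eno (enolase, SE 0.025). Each of these was higher in 6 of 6 Cu samples than in any Mn sample. Lower in Cu were ppsA at -0.11 (SE 0.024) and glnA (glutamine synthetase) at -0.10 (SE 0.028, adjusted p = 0.0132), the latter beyond all Mn samples in 3 of 6 and no longer called without Mn 0.8 mM set A, Cu 0.85 mM set A or Cu 1.0 mM set A. In channel 1 alone the calls of purM (0.051), purD (0.081) and arcC (0.055) ended with smaller values, and purF was at 0.17, still called. In channel 2 alone those of ppsA (-0.088) and glnA (-0.094) ended at about the same size. Among features without a symbol feature4795 was higher by 0.39 and feature1007 lower at -0.61.

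By list, 5 of 7 purine members were higher in Cu than in Mn (6 adjusted over the list alone), 2 of 5 of pyrimidine synthesis (3 adjusted over the list alone), and 2 of 2 of arginine fermentation. For the chaperone and proteasome list 0 of 4 passed over all features and 4 of 4 adjusted over the list alone. Camera called the purine list (adjusted p = 0.00103; adjusted p = 0.0689 with an estimated correlation) and placed flagella and chemotaxis lower (adjusted p = 0.0106; adjusted p = 0.106 with an estimated correlation, 0 of 11 members called). Against all features as background the purine call held with an estimated correlation (adjusted p = 0.0329), and flagella and chemotaxis was not called (adjusted p = 0.0874). Both backgrounds were chosen after the data were seen. Fry called the purine list (adjusted p = 0.000112) and the pyrimidine list (adjusted p = 0.00894) higher in Cu. It called flagella and chemotaxis lower (adjusted p = 0.006).

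This comparison called 349 features, 254 higher in Cu and 95 lower, with 28 named genes, 26 of them higher. It tested 2687 features, or 1281 without Mn 1.0 mM set B, and the same held at 1.0 mM. Without Mn 1.0 mM set A it called 400 (234 higher and 166 lower), and without Mn 1.0 mM set B 556 (474 higher and 82 lower). At 1.0 mM, the dose used for both metals, 103 features were called, 90 higher in Cu and 13 lower, with gdhA1 at 0.30 (SE 0.043), carB at 0.29 (SE 0.045) and purM at 0.28 (SE 0.042). In channel 1 alone these 3 calls ended, with gdhA1 at 0.18 (adjusted p = 0.162), carB at 0.12 (adjusted p = 0.475) and purM at 0.12 (adjusted p = 0.594). Without Mn 1.0 mM set A the split there was 52 higher and 57 lower, so no balance of directions can be read from that dose; without Mn 1.0 mM set B it called 576, and without a Cu sample 49 or 28. Array numbers ran by group, so a batch of arrays and a group cannot be told apart in any of these comparisons.

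**Figure D2:**
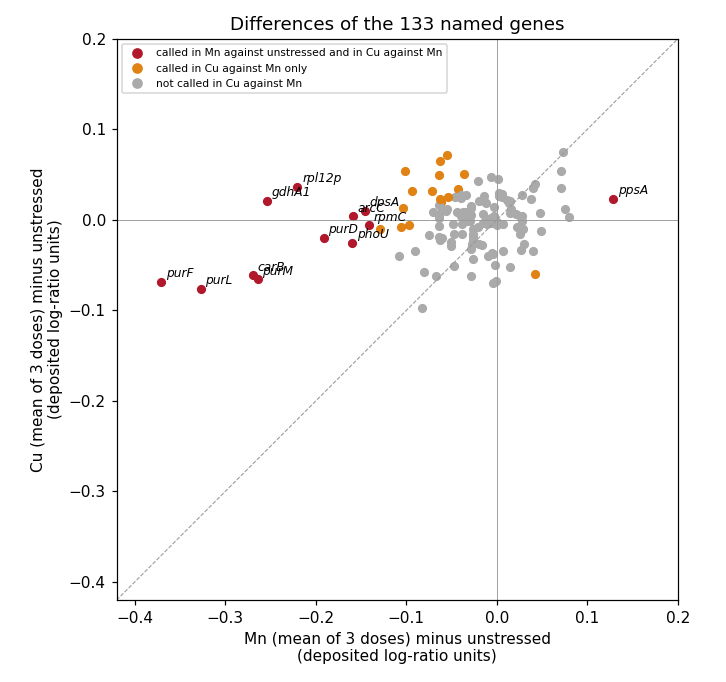
Differences from unstressed of the 133 named genes, Mn on the horizontal and Cu on the vertical axis (means of 3 doses, deposited log-ratio units), with equal differences on the dashed line; labelled genes were called under Mn. The axes share the unstressed samples, so their relation is not read; purF lies at -0.37 on the Mn axis and -0.068 on the Cu axis.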

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

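Among the tests below, those on the array with most spots at 0, on drift, on a batch of arrays, on splits of whole dose groups and on the spread between Cu samples were chosen only after the results were seen. What drew attention was a difference between the responses to the metals, by its own test: 349 features differed between Cu and Mn. Every named gene among the largest called changes under Mn also differed between the metals, Cu minus Mn, with values of 0.30 for purF, 0.27 for gdhA1, 0.26 for rpl12p, 0.25 for purL, 0.21 for carB, 0.20 for purM, 0.17 for purD, 0.16 for arcC, 0.16 for dpsA, 0.13 for phoU and -0.11 for ppsA. These genes were chosen for their Mn change, and the Mn samples enter both tests, so their passing was likely beforehand. In a fit of 2 groups, 1 of 100 drawn splits of the 12 metal samples into 6 and 6, the real split itself, called as many features. The real split called 329 and the highest other 27, so chance can be excluded if single samples are exchangeable. With the samples of a dose kept together there are 10 splits, too few for a share under 0.05; 1 of them, the real split, called 329 features and the highest other 0.

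The fall of 11 named genes under Mn was weighed against technical explanations. On a dye bias left after the exchange of dyes, 11 of 11 had a negative difference in both orientations, though those of purM, purD and arcC were smaller in channel 1. The genes were chosen on the mean of both orientations, and a dye effect common to all arrays cancels in these differences. Agreement in sign was thus likely beforehand and does not decide. The array with most spots at 0 is argued against by 10 of 10 with a ratio in its sample being still called without it; purF had no ratio there. A steady drift over the array numbers, in which Cu arrays come last, is argued against by 11 of 11 having a smaller Cu difference and a called difference between metals, though the genes were chosen for their Mn change. A batch shared by the Mn arrays alone stays open and cannot be told apart from Mn itself, since 7 of 7 groups filled an unbroken run of array numbers of their own. A response to Mn, which the design names, stays open beside it.

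Few features were called under Cu. A wider spread between Cu samples was weighed as an explanation. The root mean square SD between the samples of a group, 3 Cu groups over Mn 0.8 and 1.5 mM, had a ratio of 0.955. This lay within the bound written against that explanation, but the groups were then compared singly. Groups ranged from 0.032 to 0.041 for Cu and from 0.032 to 0.046 for Mn, so with 5 groups the test does not decide whether Cu samples vary more. The fit takes 1 variance per feature for all groups, so its SE could not show such a spread. Its median SE of 0.0364 for the Cu mean and 0.0374 for the Mn mean are near equal by construction. They do not show whether the Cu mean was less precise. A weaker response to these Cu doses than to these Mn doses stays open. The direct test between the metals bears on it for the 11 genes above, whose Cu difference was smaller, though they were chosen for their Mn change. The dose ranges differ, so metal and dose were not separated in those means. At 1.0 mM, the dose used for both metals, gdhA1, carB and purM were higher in Cu. Those calls ended in channel 1 alone.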

How the results depend on the processing

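Alternatives that kept 0 values, took values as already turned or used all features as list background were chosen only after the data were seen. The cause of the changes below was not tested unless named. With the arrays that hold sample RNA in channel 1 alone the calls were 1997 for unstressed against reference, 28 for the Mn mean, 1 for the Cu mean (not feature1107 or feature4291), 134 for Cu against Mn, 20 for Cu against Mn at 1.0 mM, 5 for Mn 1.5 against 0.8 mM, 7 for Cu 1.0 against 0.7 mM, 13, 17 and 24 for Mn at 0.8, 1.0 and 1.5 mM, and 1 and 6 for Cu at 0.7 and 1.0 mM. With those that hold it in channel 2 alone they were 1752 for unstressed against reference, 77 for the Mn mean, 1 for the Cu mean, 0 for Mn 1.5 against 0.8 mM, 2 for Cu 1.0 against 0.7 mM, 45 for Mn 1.0 mM and 4 for Cu 1.0 mM. Against the reference the dye effect does not cancel in a single orientation, which by construction also turned the sign of genes there: in channel 1 purL -0.056, arcA -0.10, purM -0.00095, purD -0.059, gdhA1 -0.00974, argH -0.21, pyrF 0.12 and dpsA -0.28, and in channel 2 rpl12p 0.091, speB 0.0024, rpmC 0.0061, sucD 0.12, secY 0.28, eno 0.26, rimI 0.13 and htr2 0.13. Taken as already turned, the values gave 2128 calls against the reference, 23 for the Mn mean, 0 for the Cu mean, 64 for Cu against Mn, 52 at 1.0 mM, 22 for Mn 1.5 against 0.8 mM, 6 for Cu 1.0 against 0.7 mM, 14, 0 and 18 for the Mn doses and 7 for Cu 1.0 mM; 141 of 182 named values changed sign, 75 of them called in either reading. With 0 values kept, calls were 186 against the reference, 0 for the Cu mean, 55 for Cu against Mn at 1.0 mM, 0 for Mn 1.5 against 0.8 mM, 40, 64 and 52 for the Mn doses and 0 for Cu 1.0 mM. With the compared groups alone they were 5 for the Cu mean, 27 for Cu against Mn at 1.0 mM, 201 for Mn 1.5 against 0.8 mM, 112, 39 and 175 for the Mn doses, and 5, 4 and 3 for the Cu doses. With complete features alone they were 1 for the Cu mean, 11 for Mn 1.5 against 0.8 mM, 1 for Cu 0.7 mM and 0 for Cu 1.0 mM, over fewer features. With each array as an observation they were 1 for the Cu mean, 8 for Mn 1.5 against 0.8 mM and 0 for Cu 1.0 mM. That fit used the consensus correlation of -0.12 between the turned arrays of a sample. No centring gave 12 for Mn 1.5 against 0.8 mM and 1 for Cu 0.85 mM; scaling gave 0 for Mn 1.5 against 0.8 mM and 0 for Cu 1.0 mM, as did the median of spots. List calls fell from 5 to 2 with an estimated correlation and were 4 against all features. Without centring purF passed for Mn 1.5 against 0.8 mM, as it did with the compared groups alone.

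Taken as already turned, the named values of opposite sign were against the reference purF -0.096, purL -0.31, arcA -0.29, purM -0.18, arcC -0.095, purD -0.22, carB -0.14, htr6 -0.12, gdhA1 -0.11, argH -0.30, pyrF 0.25, feature4007 -0.11, feature4805 -0.026, feature4433 0.054 and dpsA -0.29. For the Mn mean they were ppsA -0.0013, purF 0.15, purL 0.081, carB 0.045, purM 0.16, gdhA1 0.046, purD 0.10, phoU 0.0064, arcC 0.084, dpsA 0.0061, feature1007 -0.064, feature903 -0.11, feature4291 0.10, feature4007 0.14, carA 0.057, pyrI 0.0090, pyrB 0.0015, msrA 0.016, dnaJ 0.040, psmB 0.0048, psmA 0.010, sdhC 0.038, nuoL 0.028, sop2 -0.012, sop1 0.0015, arcA 0.0065, cheR 0.031, cheB -0.00043, uvrB 0.012, uvrA 0.030, mutL -0.026, cobN 0.011, cbiQ 0.034, cbiG -0.024, cbiT -0.018 and pyrF -0.0068. For the Cu mean they were feature1107 -0.16, feature4291 0.056, thiL 0.012, purL 0.027, htr2 -0.00091, speB -0.030, pyrB -0.044, purM 0.011, purF 0.012, purD 0.014, dpsA -0.011, msrA -0.033, psmA -0.044, psmB -0.029, rpl12p -0.059, nuoL -0.011, sdhC -0.026, bat 0.0022, sop2 -0.0079, sop1 0.0023, hop 0.014, arcC -0.024, htr6 0.00059, cheA 0.016, uvrB 0.019, uvrA 0.0041, cbiG -0.018 and cbiT -0.020. For Cu against Mn they were purF -0.14, gdhA1 -0.045, rpl12p -0.032, purL -0.054, carB -0.060, purM -0.15, purD -0.090, arcC -0.11, dpsA -0.017, feature4795 -0.080, feature4007 -0.13, feature1007 0.073 and feature903 0.092. For Cu 1.0 mM against Mn 1.0 mM they were gdhA1 -0.13, carB -0.17, purM -0.16, feature4007 -0.20, feature4795 -0.22, feature1007 0.014 and feature903 0.094. For Mn 1.5 against 0.8 mM they were feature3583 0.10, purF 0.045, ndk -0.073, purL 0.038, purB 0.17 and tmk 0.0075. For Cu 1.0 against 0.7 mM they were cca -0.081 and hutI -0.030. For Mn 0.8 mM they were purF 0.12, purL 0.043, gdhA1 0.052, feature1007 -0.098, feature903 -0.13, feature1605 0.081 and feature4291 0.12. For Mn 1.0 mM they were carB 0.13, purL 0.12, purM 0.18, feature1007 -0.014, feature903 -0.073, feature4291 0.12 and feature4007 0.20. For Mn 1.5 mM they were ppsA -0.038, purF 0.16, purL 0.081, purM 0.15, feature1007 -0.079, feature903 -0.12, feature4007 0.11 and feature4291 0.071. For Cu 0.7 mM they were bat 0.046, htr6 0.024, purL 0.064 and thiL 0.048. For Cu 0.85 mM they were purM 0.019, htr2 -0.021 and gatA 0.012. For Cu 1.0 mM they were feature1107 -0.20, speB -0.070, htr2 -0.018, purL 0.017 and purF 0.031.

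Beyond those against the reference, values not called either way also turned sign, in channel 1 alone for the Mn mean nuoL 0.0073, uvrA 0.0036, mutL -0.0069, cbiG -0.018 and cbiT -0.016, for the Cu mean dpsA -0.00074, msrA -0.012, psmA -0.020, psmB -0.019, rpl12p -0.023, hop 0.012, arcC -0.020 and uvrB 0.0025, for Mn 1.5 against 0.8 mM purB 0.0083. In channel 2 alone such values were for the Mn mean bat 0.019 and hop -0.011, for the Cu mean dnaK 0.020, dnaJ -0.032, arcA 0.021, phoU 0.011, mutL 0.0036 and cobN 0.011, for Cu 1.0 against 0.7 mM rpl12p 0.0029. With scaling they were for the Mn mean hop -0.0069, for the Cu mean dpsA -0.0037, psmB -0.0041, dnaJ -0.0055 and arcC -0.0059. With the median of spots they were for the Mn mean hop -0.012 and cbiG -0.00039. With 0 values kept the 1 such value was for the Mn mean cbiT -0.0011.

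The set letters did not clearly pair the samples. Over 21 pairs of groups the correlation of set deviations had a median of -0.039. It ran from -0.16 to 0.37, and 4 were over 0.1. Calls rose in the 4 main comparisons with the set as a block, so an effect of the set is not excluded. With the set as a block purF passed for Mn 1.5 against 0.8 mM (adjusted p = 0.0341) and arcA for the Mn mean (adjusted p = 0.0497), pyrF was at -0.0022 for the Mn mean, not called either way, and the calls were 4 for the Cu mean, 12 for Mn 1.5 against 0.8 mM and 1 for Cu 0.85 mM, and other counts stayed within 1.5 times (136 for the Mn mean, 391 for Cu against Mn, 358 against the reference).

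Leaving out each sample in turn, where a lone sample is assumed to vary like the others, gave 43 to 226 calls against the reference, 43 to 254 for the Mn mean, 0 to 2 for the Cu mean, 254 to 556 for Cu against Mn, 28 to 576 at 1.0 mM, 0 to 1 for Mn 1.5 against 0.8 mM, 26 to 64 for Mn 0.8 mM, 43 to 538 for Mn 1.0 mM, 29 to 48 for Mn 1.5 mM, 0 to 2 for Cu 0.7 mM, 0 to 2 for Cu 0.85 mM, 0 to 1 for Cu 1.0 mM and 0 for Cu 1.0 against 0.7 mM. The highest counts for the Mn mean, Mn 1.0 mM, Cu against Mn and the 1.0 mM comparison came without Mn 1.0 mM set B. That fit tested 1281 features. Where leaving out a sample turned the sign of a named value, never a called one, the ranges were against the reference dpsA -0.027 to 0.049. For the Mn mean they were pyrB -0.10 to 0.031, msrA -0.069 to 0.030, sdhC -0.084 to 0.0053, nuoL -0.067 to 0.025, bat -0.069 to 0.011, sop1 -0.073 to 0.021, hop -0.038 to 0.039, cheB -0.00092 to 0.059, mutL -0.014 to 0.065, cbiQ -0.075 to 0.0078, cbiG -0.045 to 0.057, cbiT -0.063 to 0.067 and pyrF -0.016 to 0.030. For the Cu mean they were pyrB -0.017 to 0.12, carA -0.034 to 0.067, dpsA -0.028 to 0.049, msrA -0.016 to 0.058, psmA -0.016 to 0.063, psmB -0.020 to 0.041, dnaK -0.045 to 0.032, dnaJ -0.025 to 0.036, rpl12p -0.014 to 0.087, nuoL -0.0034 to 0.089, sdhC -0.017 to 0.072, hop -0.019 to 0.015, arcA -0.046 to 0.025, arcC -0.0072 to 0.015, phoU -0.075 to 0.025, mutL -0.055 to 0.024, cbiQ -0.014 to 0.069, cbiG -0.022 to 0.079, cbiT -0.039 to 0.091 and cobN -0.029 to 0.019. Among named values over all these settings, the already-turned reading apart, 2650 kept direction and side of the threshold, 116 lost the call, 16 gained it and 94 changed sign, 78 of them called in neither setting. Signal over background is unknown for these values.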

Other observations

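Other called differences between the metals also included gyrA and gyrB, the DNA gyrase subunits, higher in Cu than in Mn at 0.077 and 0.091, infB, a translation initiation factor, at 0.081, secY, a subunit of the protein export channel, at 0.10, and citZ (citrate synthase) at 0.13. These genes fall outside the naming rule and were chosen after their values were seen. In the list of the citric acid cycle and 2-oxoacid oxidation, made after the values were first seen, 3 of 7 members were higher in Cu, citZ among them. Camera did not call it against the named genes (adjusted p = 0.321), but did against all features (adjusted p = 0.0451; adjusted p = 0.443 with an estimated correlation), a background added after the data were seen. Of 12 aminoacyl-tRNA synthetases and 6 genes of histidine synthesis none was called in the 4 main comparisons. For Cu against Mn the camera adjusted p were 0.765 and 0.312. Fry called the synthetases higher in Cu (adjusted p = 0.0309), and the citric acid cycle list too (adjusted p = 0.0309). It did not call histidine synthesis (adjusted p = 0.0702). Under Mn, and in unstressed against the reference, fry called the synthetases lower (adjusted p = 0.0433 and 0.0349). Of 12 genes of other amino acid synthesis gdhA1 was higher and glnA lower in Cu (camera adjusted p = 0.321). For the difference between the metals in the effect of the highest against the lowest dose limma called 0 features, with 369 at an unadjusted p under 0.05 against 134.4 by chance, so a difference is not excluded.

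A hypothesis was that genes higher in the knockout than in the reference fall under Mn, as purF and purL did. It was tested with the level taken from the Cu samples, since unstressed samples enter both the level and the Mn difference; this test was written before its result was seen. Across 2687 features the correlation was -0.075 (Spearman 0.018), and with the unstressed level it was -0.27, so shared samples may account for the latter and the hypothesis was not borne out over all features. Across the 133 named genes it was -0.36, a value looked at in the same step and not tested further, and features are not independent replicates. With every RNA sample scaled to the same spread the correlation was -0.21, which met the bound of -0.2 set beforehand. It passed that bound by less than a margin for its spread that treats features as independent. Compressed ratios in the Mn samples thus stay undecided. Their SD ran from 0.0833 to 0.104, against 0.0643 and 0.0838 unstressed, so the ranges overlapped at Mn 1.5 mM set B. Noise also widens an SD, so these values do not decide on a narrowing of the spread. Scaling shrinks samples with a wider spread, which can by itself lower the correlation, so the value after scaling does not decide either. Slopes on the Cu level ran from 0.829 to 1.12 for Mn and were 0.98 and 1.06 unstressed. Every Mn sample but 1.0 mM set B (1.12) had a slope below both unstressed samples. Compression and a fall of the genes with higher ratios would each lower a slope, so the slopes cannot tell them apart.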
